A study of Mus musculus with 8 samples.

How the data were processed

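RNA was extracted with RNeasy columns from the brains of PBS-perfused mice, and libraries were made from total RNA with an Illumina kit, per the labels' protocols. The wording of the labels leaves open whether RNA came from a part of each brain or from some of the brains, and which part. The strain that carries CAA, the sex of the animals, the strandedness of the libraries and the time of collection are not given in the sources used here. A deposited table gives, for 54532 mouse genes, raw counts of reads per gene in each of 8 libraries, made by the authors with HISAT2 2.0.5 and featureCounts 1.5.0-p3 against the mm10 build, per the submitters' processing notes; their parameters and the annotation release are not given in the sources used here. A separate deposited table holds FPKM values per gene and library, made by the authors from those counts; dividing count and gene length by FPKM gave library denominators that equal DESeq2's robust library sizes (ratio 1). Of the gene identifiers 54495 are in GENCODE vM21, and 98.3% of those have the same chromosome, start and end there. Coordinates are those of the deposited tables. The counts had no entry without a gene name.

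Samples were grouped by their titles into WT mock, WT stress, CAA mock and CAA stress, 2 libraries each. The libraries held 17275201 to 18894657 counts, and 25086 genes had none in any library. Pairs of libraries differed by more than counting noise (chi-square per degree of freedom 8.70 to 73.9), so no library was counted as a repeat of another. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups (minimum count 10, minimum total 15; 17182 genes), and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to the 4 group means over all 8 libraries, which share 1 estimate of the spread (4 residual degrees of freedom, prior degrees of freedom 7.29, common biological coefficient of variation 0.206). The 7 comparisons were stress in WT, stress in CAA, CAA under mock, CAA under stress, the interaction, and the averages of the stress effects and of the CAA effects. Two-sided p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Standard errors are those of the log2 fold change, and CPM values are TMM-normalised.

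Of 45 gene lists for cell types, brain regions, stress and RNA quality, taken from general knowledge, the 43 with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, adjusted over lists within a comparison); 1 of the 679 listed symbols was absent from the count table. The groups, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule names, per comparison, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold, with a mean of at least 1 CPM, no clone-style symbol and no overlap between the compared libraries. Where fewer than 5 pass, it names the 5 with the smallest unadjusted p as values. Of each list it names up to 4 members past the threshold or else the 2 with the smallest p as values, and it always reports App, Thy1, Prnp, Gfap, Fkbp5, S100a8, S100a9, Mpo, Padi4 and the sex-linked genes. A further gene that the rule names as a list member is not reported here. Other genes and the lists given with a median under each alternative were chosen after their values were seen.

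The other settings fixed in advance were DESeq2's size factors in edgeR, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, only the libraries compared, limma on log2 FPKM with a pseudocount of 1 or 0.1, camera with an estimated correlation, and genes of at least 10 mean CPM for the correlations. Each library was also left out in turn, where the lone library of a group is assumed to vary like the others. A term for sex, the male libraries alone, and the omission of the 2 libraries low in striatal markers were added after the data were seen. A count of 0 was given a floor of 3 counts.

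The tests were run on simulated counts for the 17182 genes, with 200 genes changed by known factors. For CAA averaged, 61.8%, 80.3% and 98.5% of the genes changed 2-fold, 4-fold and 8-fold were recovered. For stress averaged, with genes changed in WT stress alone, the shares were 10.3%, 54.5% and 84.8%. They were 39.7%, 77.3% and 92.4% for stress in WT, 47.1%, 80.3% and 83.3% for stress in CAA, 32.4%, 77.3% and 86.4% for CAA under mock, 25%, 69.7% and 87.9% for CAA under stress, and 11.8%, 71.2% and 68.2% for the interaction. False calls made up 7.51% of the calls for CAA averaged and 14.7% for stress averaged. For the others, in the order above, they made up 10.9%, 9.09%, 13.3%, 10.4% and 5.66%. These shares lie above the aim of 0.05, or 5%, so an edgeR adjusted p just under the threshold is smaller than these simulated counts bear out.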

Results

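Messenger RNA was sequenced from the brains of wild-type (WT) mice and of mice described as having cerebral amyloid angiopathy (CAA), a disease in which amyloid-beta builds up in the walls of cerebral blood vessels. Mice of both kinds were either subjected to chronic restraint stress or mock-treated. The stated interest was how chronic stress acts on CAA and on neutrophil extracellular traps, the webs of chromatin and granule proteins that neutrophils release. The 8 libraries fell into 4 groups of 2: WT mock, WT stress, CAA mock and CAA stress. Of their gene counts 99.9% fell on the 17182 genes tested. Libraries are named by group and replicate number, so that WT mock 1 is WT mock replicate 1. Each library counts as 1 replicate; the titles number the replicates without saying that each came from a separate animal, so p-values measure only the spread between these samples. With 2 libraries against 2, an exact two-sided permutation test of a single value cannot go below p = 0.333.

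The non-coding RNA Xist, which coats the inactive X chromosome of females, had 4575 counts in WT mock replicate 1 and 3340 in CAA stress replicate 1, against 0 to 24 in the other 6 libraries. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in those 2 libraries and 2260 to 2833 in the others, so that 2 libraries were female and 6 male by these counts; "in males" means in those 6. Markers of brain regions differed between replicates of 1 group. Which part of each brain gave the RNA is not given. The 12 striatal markers, among them the dopamine receptors Drd1 and Drd2, lay at a mean log2 level of -2.18 in WT mock replicate 1 and -1.98 in CAA mock replicate 2, against 0.05 to 1.03 in the other 6 libraries. These 2 are called the low-striatum pair. Each gene was centred on its mean over the 8 libraries. The 14 hypothalamic markers lay at -2.43 and -1.40 in the same 2 libraries. The 9 olfactory bulb markers were low in 4 libraries, WT mock replicate 1 (-1.90), CAA mock replicate 1 (-1.03), CAA mock replicate 2 (-1.18) and CAA stress replicate 1 (-0.77), and lay at 0.85 to 1.49 in the others. The 16 choroid plexus markers were highest in WT stress replicate 2 (2.03) and CAA stress replicate 1 (1.63). Genes of the mitochondrial genome took 6.10% of counts in CAA stress replicate 2 and 7.89% to 9.99% in the other 7 libraries.

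**Figure D1:**
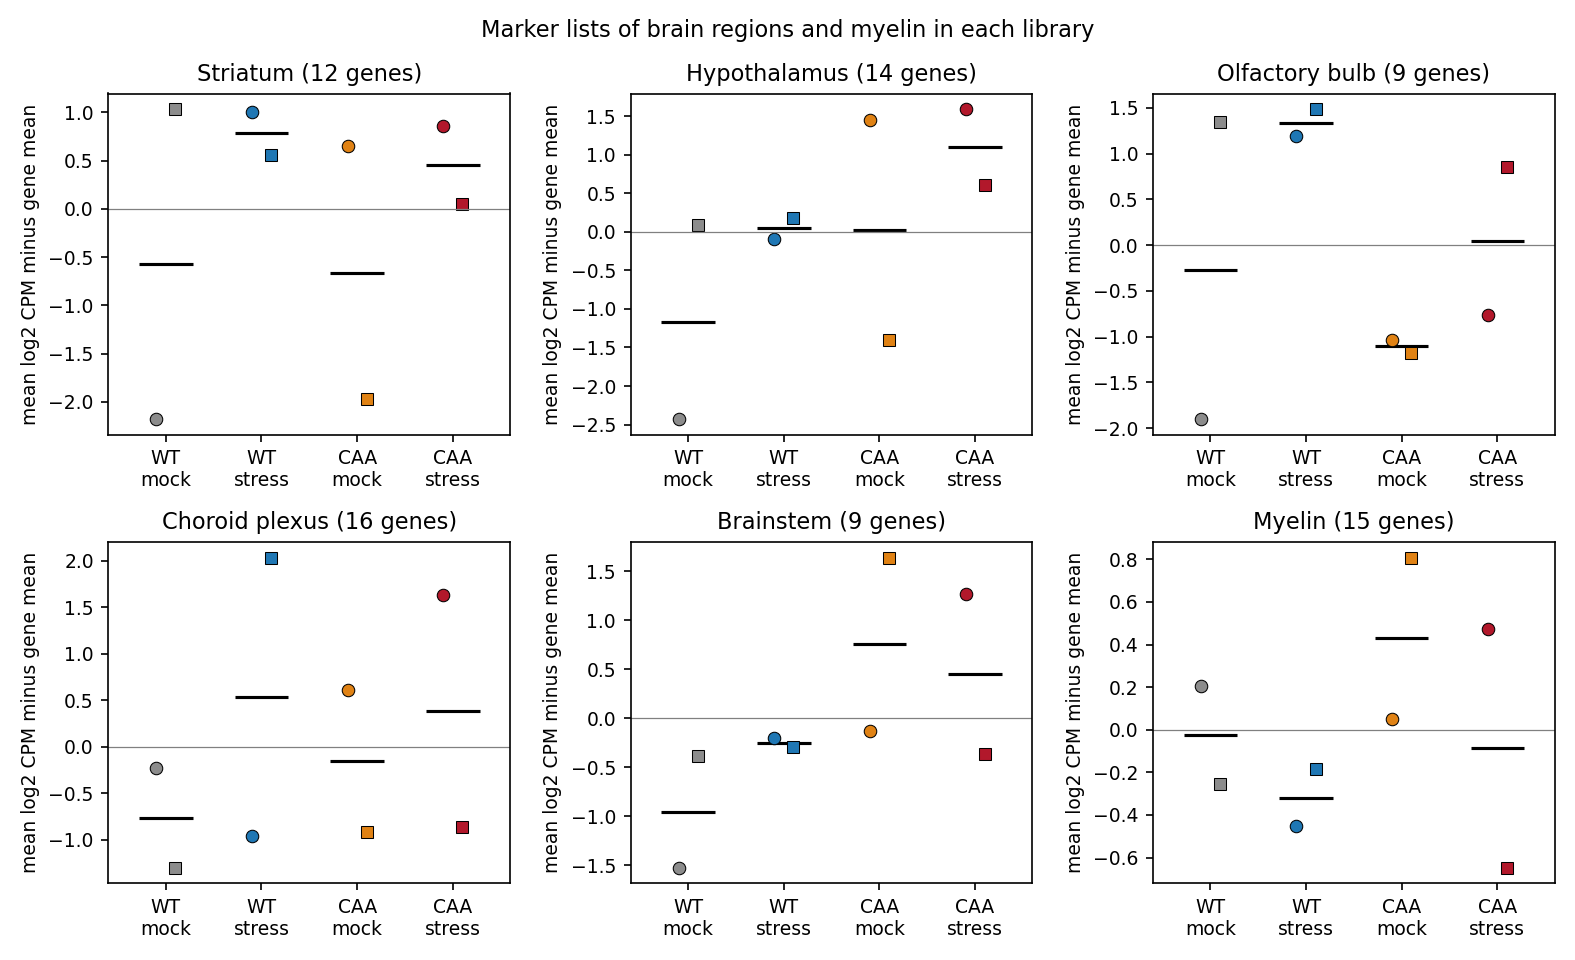
Mean log2 CPM of 6 marker lists (striatum 12 genes, hypothalamus 14, olfactory bulb 9, choroid plexus 16, brainstem 9, myelin 15) in each of the 8 libraries, each gene minus its mean over the libraries. Striatal markers lie at -2.18 in WT mock replicate 1 and -1.98 in CAA mock replicate 2.

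Averaged over mock and stress, 2 genes differed between CAA and WT brains. Wdfy1, which encodes an endosomal adaptor of Toll-like receptor signalling, rose 4.93-fold, from 11.3 ± 1.35 to 55.7 ± 7.59 CPM (TMM-normalised counts scaled to library size; SD, n = 4). Ngef, which encodes the neuronal guanine nucleotide exchange factor ephexin-1 that acts downstream of Eph receptors, fell by 2.20 on the log2 scale, from 285 ± 27.3 to 62.3 ± 14.7 CPM (SD, n = 4). The log2 fold change of Wdfy1 was 2.30 ± 0.14 (SE; edgeR adjusted p = 5.15e-05), and that of Ngef was -2.20 ± 0.17 (SE; edgeR adjusted p = 4.44e-04). All 4 CAA libraries lay above all 4 WT libraries for Wdfy1 and below them for Ngef. Both genes are on chromosome 1 of the mm10 build, on the minus strand: Wdfy1 (ENSMUSG00000073643) from 79702262 to 79776143 and Ngef (ENSMUSG00000026259) from 87476834 to 87573870. Neu2 (ENSMUSG00000079434), a cytosolic sialidase gene, lies on the plus strand from 87509889 to 87597845. It overlaps Ngef by 63982 bases. Its level was 5.13 ± 0.671 CPM in WT and 1.17 ± 0.543 CPM in CAA (SD, n = 4; log2 fold change -2.15 ± 0.33, edgeR adjusted p = 0.206). Whether the counting used strand is not given, so reads of Ngef and of Neu2 cannot be told apart where the genes overlap. Wdfy1 overlaps Mrpl44 by 126 bases.

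In the averaged comparison genes with the next smallest p did not pass in edgeR. Thy1, a neuronal surface glycoprotein whose promoter is widely used to drive transgenes in mouse neurons, lay at 465 ± 29.6 CPM in WT and 816 ± 150 CPM in CAA (SD, n = 4; log2 fold change 0.80 ± 0.13, edgeR adjusted p = 0.206, DESeq2 adjusted p = 1.97e-05); it passed in males (0.99, edgeR adjusted p = 0.0437). The strain is not given. Gene counts cannot separate a gene's reads from those of a transgene that holds its sequence, which bears on Thy1, App and Prnp. Nr2f2, a nuclear receptor of developing interneurons and vessels, lay at 10.6 ± 2.08 and 23.8 ± 4.58 CPM (log2 fold change 1.16 ± 0.19, edgeR adjusted p = 0.206), and passed without the low-striatum pair (1.46, edgeR adjusted p = 0.0433). App, the amyloid precursor gene, had a log2 fold change of 0.01 ± 0.11 and Prnp, the prion protein gene, had 0.06 ± 0.10. The sign for App changed without WT mock 2 (-0.047) or CAA stress 2 (-0.016). Gfap, the intermediate filament of astrocytes, lay at 218 ± 71.8 CPM in WT and 409 ± 187 CPM in CAA (SD, n = 4; log2 fold change 0.86 ± 0.21, edgeR adjusted p = 0.508, DESeq2 adjusted p = 0.00417). edgeR called 2 genes and DESeq2 49 (29 higher, 20 lower). In edgeR 1439 genes had an unadjusted p under 0.05 (859 expected by chance in each comparison). Wdfy1 and Ngef passed without each library in turn, and without WT mock 2 the count was 5.

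**Figure D2:**
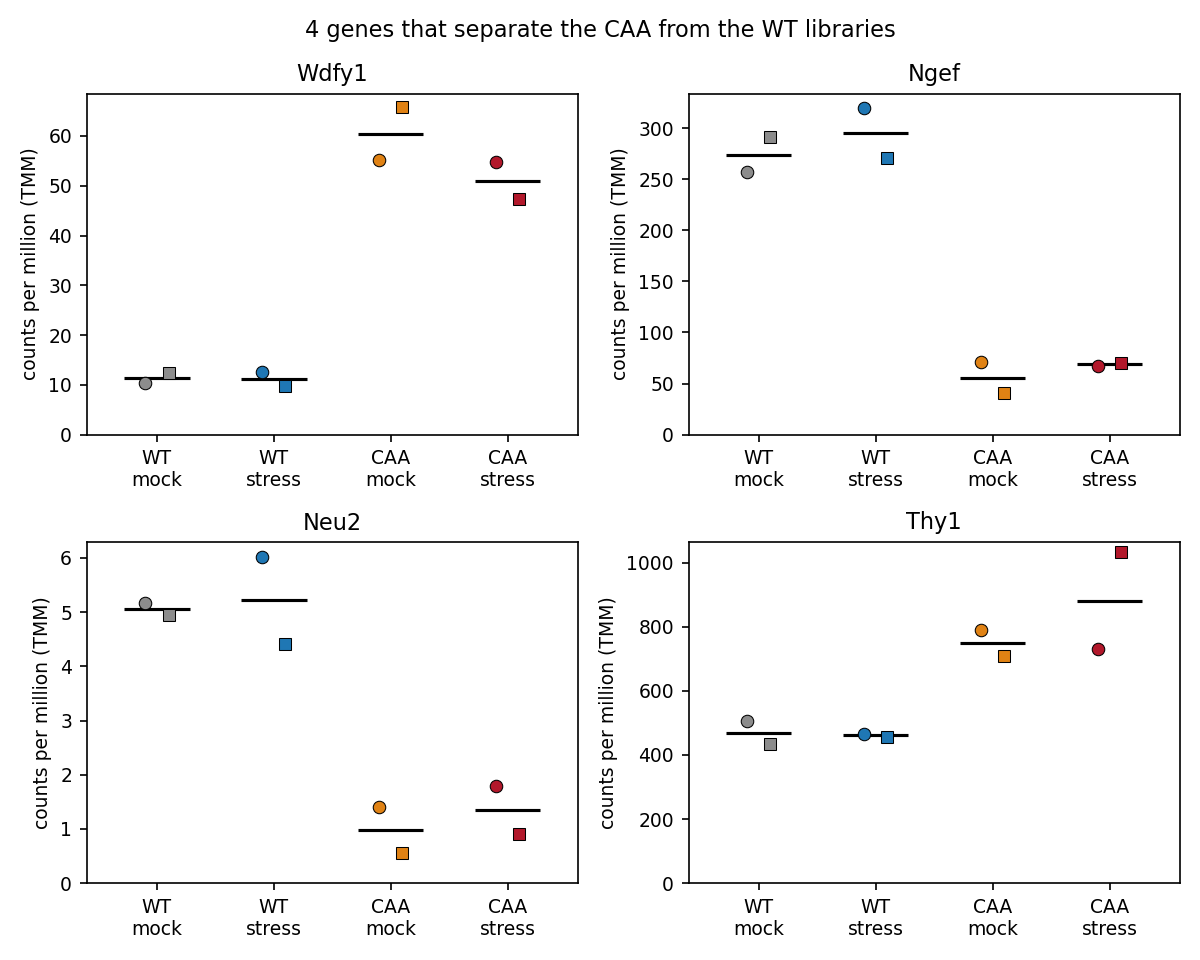
TMM-normalised CPM of Wdfy1, Ngef, Neu2 and Thy1 in each of the 8 libraries by group (circle, replicate 1; square, replicate 2; bar, mean of the 2). The CAA libraries lie above the WT libraries for Wdfy1 (means 55.7 and 11.3 CPM) and below them for Ngef (62.3 and 285 CPM).

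Several gene lists passed the test for the averaged genotype effect with the preset correlation. None passed with an estimated correlation (adjusted p = 0.601 for each list given here). Of the 22 genes of disease-associated microglia, which microglia raise around amyloid, 18 were higher in CAA (median log2 fold change 0.26, mean 0.54, camera adjusted p = 2.23e-05, adjusted p = 0.601 with an estimated correlation). Apoe, the main apolipoprotein of the brain, lay at 1276 ± 146 CPM in WT and 2005 ± 508 CPM in CAA (SD, n = 4; log2 fold change 0.66 ± 0.17). Itgax, an integrin of activated microglia, had 1 to 5 counts per WT library and 5 to 25 per CAA library. All 18 fibroblast and matrix genes were higher (median 0.41, camera adjusted p = 8.94e-06). Among them the matrix protein genes Fbln1 and Dcn had log2 fold changes of 0.57 ± 0.17 and 0.68 ± 0.22. Of the 11 oligodendrocyte precursor genes 9 were higher (median 0.11, camera adjusted p = 0.00363), led by the lineage factor Olig1 at 0.58 ± 0.15 and by C1ql1 at 0.65 ± 0.20. Reactive astrocyte genes were higher in 13 of 16 (median 0.07, camera adjusted p = 0.0224), with Gfap above and the complement gene C4b at 0.54 ± 0.18. So were 10 of 12 general astrocyte genes (median 0.21, camera adjusted p = 0.0319). All 15 myelin genes were higher (median 0.41, camera adjusted p = 0.00104), with Cnp at 0.45 ± 0.22 and Cldn11 at 0.47 ± 0.25. Immediate early genes, which neurons switch on with activity, were lower in 16 of 19 (median -0.39, camera adjusted p = 5.5e-05). Egr1 lay at -0.61 ± 0.16 and Fosl2 at -0.57 ± 0.17, while Jun lay at 0.65 ± 0.13. Genes responsive to glucocorticoids were higher in 18 of 22 (median 0.19, camera adjusted p = 0.00256), with Ddit4 at 0.52 ± 0.15 and Klf15 at 0.51 ± 0.15. Olfactory bulb markers were lower in 7 of 9 (median -1.59, camera adjusted p = 0.00324).

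In camera with the preset correlation 20 of 43 lists passed for the averaged genotype effect, 14 higher and 6 lower; with an estimated correlation 0 lists passed in each of the 7 comparisons. Where a call was lost, the brackets hold the list's median and its camera adjusted p, or that p alone. Over all genes tested 0 genes of these lists passed in edgeR. Adjusted over the list alone, 3 oligodendrocyte precursor genes, 1 reactive astrocyte gene, 3 immediate early genes (Jun higher, Egr1 and Fosl2 lower) and 0 genes of the microglial, fibroblast, myelin, glucocorticoid and olfactory bulb lists passed. The microglial median was 0.17 without CAA stress 1 and 0.16 in males. The fibroblast median was 0.15 without CAA mock 2, 0.21 without CAA stress 2 and 0.21 without the low-striatum pair. The oligodendrocyte precursor median was 0.23 without WT mock 2, 0.22 without WT stress 2, 0.22 without CAA stress 2, 0.26 in males (camera adjusted p = 0.0532) and 0.052 without the low-striatum pair. The myelin call was lost without CAA mock 2 (0.19, 0.286) or CAA stress 1 (0.040, 0.494), and its median was 0.67 without CAA stress 2 and 0.17 in males. The immediate early median was -0.21 without WT mock 1, -0.19 in males (camera adjusted p = 0.114) and -0.17 without the low-striatum pair (0.293). The olfactory bulb call was lost without WT mock 2 (-0.19, 0.953), and its median was -2.75 without CAA stress 2. In males its genes Omp (-2.56, edgeR adjusted p = 0.00829) and Cdhr1 (-1.51, 0.00829) passed over all genes tested. The glucocorticoid call was lost without WT mock 1 (0.075), WT stress 2 (0.0509), CAA mock 2 (0.11, 0.0792) or CAA stress 1 (0.012, 0.218). Its median was 0.29 without WT mock 2, 0.32 without CAA stress 2, -0.020 in males (camera adjusted p = 0.864) and 0.026 without the low-striatum pair (camera adjusted p = 0.29). The reactive astrocyte call was lost without WT mock 2 (0.21, 0.117), WT stress 2 (0.13, 0.134), CAA mock 2 (0.042, 0.557), CAA stress 2 (0.045, 0.162) or the low-striatum pair (0.232). Its median was 0.22 without WT mock 1, 0.18 without WT stress 1, 0.26 without CAA mock 1, 0.20 without CAA stress 1 and 0.22 in males. Without CAA mock 2 the count of lists was 12.

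Beside these lists, markers of the hypothalamus (13 of 14, median 0.70, camera adjusted p = 0.00137), the thalamus (11 of 12, median 0.51, camera adjusted p = 0.0151) and the brainstem (7 of 9, median 0.99, camera adjusted p = 0.00755) were higher in CAA (adjusted p = 0.601 with an estimated correlation for each). The hypothalamic call was lost without WT mock 1 (0.40, 0.171), CAA mock 1 (-0.44, 0.196) or in males (0.25, 0.67). Its median was 3.08 without WT mock 2. The thalamic call was lost without WT mock 2 (0.39, 0.0928), WT stress 1 (0.36, 0.177), CAA mock 2 (0.18, 0.538), CAA stress 1 (0.044, 0.708), in males (0.23, 0.379) or without the low-striatum pair (0.35, 0.286). Its median was 0.89 without WT stress 2 and 0.83 without CAA stress 2. The brainstem call was lost without WT mock 1 (0.395), WT stress 2 (0.0599), CAA mock 2 (0.48, 0.116), in males (0.43, 0.823) or without the low-striatum pair (0.45, 0.675). Its median was 0.43 without CAA stress 1. Of these 3 lists 0 genes passed in edgeR over all genes tested and, adjusted over the list alone, 1 hypothalamic gene.

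Genes of ribosomal proteins (24 of 30, median 0.17, camera adjusted p = 0.000959) and nuclear genes of the respiratory chain (21 of 25, median 0.19, camera adjusted p = 0.000959) were higher in CAA, and genes of the mitochondrial genome (12 of 13, median -0.22, camera adjusted p = 0.00256) and of synapses (14 of 20, median -0.17, camera adjusted p = 0.00157) lower. Each of the 4 had an adjusted p = 0.601 with an estimated correlation, and 0 of their genes passed in edgeR over all genes tested or adjusted over the list alone. The ribosomal call was lost without WT mock 1 (0.12, 0.075), CAA stress 1 (0.056, 0.261), in males (0.024, 0.902) or without the low-striatum pair (0.14, 0.0541). Its median was 0.27 without CAA stress 2. The nuclear call was lost without CAA stress 1 (0.016, 0.645) or in males (0.020, 0.823). Its median was 0.11 without CAA mock 1 and 0.31 without CAA stress 2. The mitochondrial call was lost without CAA stress 2 (-0.12, 0.502). Its median was -0.15 without CAA mock 1, -0.35 without CAA stress 1, -0.40 in males and -0.35 without the low-striatum pair. The synaptic call was lost without CAA mock 2 (-0.071, 0.139), CAA stress 1 (-0.069, 0.0999), in males (-0.063, 0.417) or without the low-striatum pair (-0.047, 0.29). Its median was -0.088 without WT stress 1.

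In mock-treated mice, CAA brains had 5.34-fold more Wdfy1 RNA than WT brains (log2 fold change 2.42 ± 0.20, n = 2 per group, edgeR adjusted p = 0.0013), and Ngef fell by 2.30 ± 0.24 on the log2 scale (edgeR adjusted p = 0.0098). Disease-associated microglial genes were higher in 20 of 22 (median 0.38, mean 0.83, camera adjusted p = 2.92e-08, adjusted p = 0.587 with an estimated correlation). The chemokine gene Ccl6 had a log2 fold change of 1.82 ± 0.50. Itgax had 1 and 1 counts in WT against 7 and 25 in CAA, and Clec7a, a pattern receptor, had 0 and 4 against 17 and 39. All 12 markers of excitatory forebrain neurons were lower (median -0.40, camera adjusted p = 1.61e-06), among them the cortical transcription factor Cux2 at -0.64 ± 0.22. Immediate early genes were lower in 15 of 19 (median -0.59, camera adjusted p = 7.99e-06, adjusted p = 0.587 with an estimated correlation for both lists), with Egr1 at -0.72 ± 0.23 and Ier5 at -0.60 ± 0.23. Markers of the thalamus (12 of 12, median 0.73, camera adjusted p = 0.00581), the brainstem (9 of 9, median 1.47, camera adjusted p = 0.000193) and the hypothalamus (11 of 14, median 0.56, camera adjusted p = 0.002) were higher there (adjusted p = 0.587 with an estimated correlation for each). Thalamic markers lay at 0.81 in CAA mock 2 and -0.29 in CAA mock 1, and brainstem markers at 1.64 and -0.13. The thalamic call was lost without WT mock 2 (0.51, 0.198), CAA mock 2 (-0.035, 0.972) or without the low-striatum pair (0.18, 0.575). Its median was 1.13 without CAA mock 1. The brainstem call was lost without WT mock 1 (1.48, 0.251), CAA mock 2 (0.38, 0.167) or without the low-striatum pair (-0.21, 0.94). Its median was 2.24 without WT mock 2. The hypothalamic call was lost without WT mock 1 (0.019, 0.977), CAA mock 1 (-1.13, 0.953) or in males (0.023, 0.811). Its median was 4.98 without WT mock 2, 1.08 without CAA mock 2 and 0.35 without the low-striatum pair. Of these 3 lists 0 genes passed in edgeR over all genes tested and, adjusted over the list alone, 1 hypothalamic gene. The striatal markers were low in 1 library of each group, WT mock 1 and CAA mock 2. Thy1 had a log2 fold change of 0.67 ± 0.18 (edgeR adjusted p = 0.998).

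In that comparison edgeR called Wdfy1 and Ngef alone and DESeq2 19 genes (5 higher, 14 lower). In edgeR 688 genes had an unadjusted p under 0.05 (859 expected). Serpinb8, a protease inhibitor gene, Jcad, of endothelial junctions, and Myl4, a myosin light chain, followed with log2 fold changes of -1.95 ± 0.33 (edgeR adjusted p = 0.539), -0.78 ± 0.14 and -1.11 ± 0.20 (both edgeR adjusted p = 0.640). Camera with the preset correlation called 21 lists (17 higher, 4 lower) and with an estimated correlation 0. Over all genes tested 0 genes of these 3 lists passed in edgeR, and adjusted over the list alone 3 microglial genes did. The count of lists was 13 without WT mock 1 and 13 without CAA mock 2. The microglial median was 0.25 without CAA mock 2. The excitatory neuron call was lost without WT mock 1 (-0.20, 0.0573), and its median was -0.64 without WT mock 2 and -0.19 in males. The immediate early call was lost without WT mock 1 (-0.19, 0.095) or CAA mock 2 (-0.22, 0.324) and in males (-0.18, 0.0868). Without the low-striatum pair, which leaves CAA mock 1 against WT mock 2, the excitatory neuron list had a median of -0.15 and the immediate early list a median of 0.052. Ngef lost its call without WT stress 1 (edgeR adjusted p = 0.0548), WT stress 2 (0.0557), CAA stress 1 (0.0663) or CAA stress 2 (0.0627), libraries that enter through the shared estimate of spread. It also lost it with only the libraries compared (edgeR, 0.26) and in limma on log2 FPKM with a pseudocount of 1 (0.0589) or 0.1 (0.0602).

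Under mock treatment, genes of myelin (15 of 15, median 0.50, camera adjusted p = 0.000144), of ribosomal proteins (30 of 30, median 0.21, camera adjusted p = 3.12e-06) and of the nuclear part of the respiratory chain (25 of 25, median 0.14, camera adjusted p = 0.00712) were higher in CAA and those of synapses (19 of 20, median -0.27, camera adjusted p = 3.77e-06) lower. With an estimated correlation the nuclear list had an adjusted p = 0.684 and the other 3 an adjusted p = 0.587. In edgeR 0 of their genes passed over all genes tested or adjusted over the list alone. The myelin call was lost without WT mock 2 (0.30, 0.171), CAA mock 2 (-0.012, 0.764) or without the low-striatum pair (0.28, 0.0748). Its median was 0.82 without CAA mock 1 and 0.85 with a term for sex. The ribosomal call was lost without WT mock 1 (0.082, 0.0573). Its median was 0.32 without WT mock 2 and 0.085 in males. The nuclear call was lost without WT mock 1 (0.14, 0.0573) or CAA mock 1 (0.059, 0.796). Its median was 0.22 without CAA mock 2, 0.26 with a term for sex and 0.22 without the low-striatum pair. The synaptic call was lost without CAA mock 2 (-0.19, 0.0608) or without the low-striatum pair (-0.11, 0.387). Its median was -0.41 without CAA mock 1.

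In stressed mice, Wdfy1 was 4.55-fold higher in CAA (log2 fold change 2.19 ± 0.20, n = 2 per group, edgeR adjusted p = 0.00349) and Ngef fell by 2.10 ± 0.24 on the log2 scale (edgeR adjusted p = 0.0221). Fibroblast and matrix genes were higher in 17 of 18 (median 0.54, camera adjusted p = 2.92e-05), with Fbln1 at 0.99 ± 0.25 and the basement membrane collagen Col4a2 at 0.71 ± 0.22. Genes of the mitochondrial genome, subunits of the respiratory chain, were lower in 10 of 13 (median -0.43, camera adjusted p = 3e-04, adjusted p = 0.812 with an estimated correlation for both lists), with mt-Nd1 at -0.60 ± 0.19 and mt-Nd2 at -0.55 ± 0.18. In edgeR 0 genes of these lists passed over all genes tested, and adjusted over the list alone 1 fibroblast gene did. The mitochondrial share of counts was 6.10% in CAA stress 2, and without that library the mitochondrial list had a median of -0.18 (camera adjusted p = 0.993) and the fibroblast list a median of 0.27 (0.0576). Without CAA stress 1 the medians were -0.67 and 0.85, and so they were in males. Respiratory chain genes of the nucleus were higher (18 of 25, median 0.19, camera adjusted p = 0.0345), and smooth muscle genes lower (9 of 11, median -0.36, camera adjusted p = 0.0345) (adjusted p = 0.812 with an estimated correlation for both). The nuclear call was lost without WT stress 2 (0.20, 0.0819), CAA stress 1 (-0.11, 0.21), with a term for sex (0.025, 0.613) or in males (-0.11, 0.212). Its median was 0.41 without CAA stress 2. The smooth muscle call was lost without WT stress 2 (-0.36, 0.131), CAA stress 2 (-0.40, 0.142) or with a term for sex (-0.23, 0.0604). Genes of erythrocytes (8 of 8, median -1.33, camera adjusted p = 0.0345) and markers of the olfactory bulb (9 of 9, median -1.09, camera adjusted p = 0.0345) were lower there (adjusted p = 0.812 with an estimated correlation for both). The erythrocyte call was lost without WT stress 1 (-0.036, 0.788), CAA stress 2 (-1.10, 0.278) or without the low-striatum pair (-1.33, 0.0628). Its median was -2.18 without CAA stress 1, -2.01 with a term for sex and -2.18 in males. The olfactory bulb call was lost without WT stress 2 (-0.78, 0.182), CAA stress 1 (-0.64, 0.279) or with a term for sex (-0.32, 0.613). Its median was -3.02 without CAA stress 2 and -0.64 in males. Of these 4 lists 0 genes passed in edgeR over all genes tested and 0 adjusted over the list alone. Disease-associated microglial genes were higher in 15 of 22 (median 0.15, camera adjusted p = 0.251). Thy1 had a log2 fold change of 0.93 ± 0.18 (edgeR adjusted p = 0.579, DESeq2 adjusted p = 0.0051).

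edgeR called those 2 genes and DESeq2 11 (7 higher, 4 lower), and 1413 had an edgeR unadjusted p under 0.05. The next genes, the mitochondrial transfer RNA mt-Tc at -1.15 ± 0.22 and the neurexophilin Nxph4 at 1.29 ± 0.27, had an edgeR adjusted p = 0.579. Wdfy1 lost its call without WT stress 1 (edgeR adjusted p = 0.0622) or WT stress 2 (0.192), and Ngef without WT stress 1 (0.490), WT stress 2 (0.198), CAA stress 1 (0.487), CAA stress 2 (0.292), with a term for sex (0.139) or in males (0.241). On log2 FPKM with a pseudocount of 1 or 0.1 limma called neither Ngef (adjusted p = 0.137 and 0.148) nor Wdfy1 (0.0605 and 0.0567). Camera with the preset correlation called 7 lists (3 higher, 4 lower), and 12, 11 and 14 without WT stress 1, WT stress 2 and CAA stress 2.

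Chronic stress in WT mice was compared with mock treatment in 2 libraries against 2. Antigen presentation genes were higher under stress in 11 of 15 (median log2 fold change 0.46, camera adjusted p = 5.5e-05, adjusted p = 0.587 with an estimated correlation). They were led by Cd74, the invariant chain of MHC class II, at 1.61 ± 0.43 and by the class II gene H2-Aa at 2.31 ± 0.77. Genes of border macrophages and monocytes (6 of 9, median 0.23, camera adjusted p = 0.0285) and of erythrocytes (6 of 8, median 1.17, camera adjusted p = 0.0328) were higher there (adjusted p = 0.587 with an estimated correlation for both). All 3 of these lists had their highest level in WT stress 1, at 0.44, 0.64 and 1.67. The border macrophage call was lost without WT mock 1 (0.76, 0.0523), WT mock 2 (0.60, 0.242), WT stress 1 (-0.28, 0.485), with a term for sex (0.50, 0.119) or without the low-striatum pair (0.76, 0.0564). Its median was 0.88 without WT stress 2 and 0.76 in males. The erythrocyte call was lost without WT mock 1 (1.57, 0.0761), WT mock 2 (0.92, 0.405), WT stress 1 (-0.11, 0.477), CAA mock 1 (1.17, 0.0525), CAA mock 2 (1.17, 0.053) or without the low-striatum pair (1.57, 0.117). Its median was 1.77 with a term for sex. Genes responsive to glucocorticoids, the hormones of the stress response, were higher in 16 of 22 (median 0.24, camera adjusted p = 0.0019), with the lipase inhibitor Angptl4 at 0.85 ± 0.30 and Zbtb16 at -0.62 ± 0.26. Homeostatic microglial genes were lower in 11 of 12 (median -0.24, camera adjusted p = 0.0072, adjusted p = 0.587 with an estimated correlation for both lists), with Olfml3 at -0.40 ± 0.22 and the growth factor receptor Csf1r at -0.29 ± 0.20. Chemokine, cytokine and adhesion genes gave 4 of 7 higher (median 0.04, mean 0.89, camera adjusted p = 0.0271, adjusted p = 0.587 with an estimated correlation). The monocyte attractant Ccl2 had 2 and 3 counts in mock against 75 and 11 under stress, and the adhesion gene Icam1 lay at 1.29 ± 0.48. All 16 choroid plexus markers were higher under stress (median 1.78, camera adjusted p = 2.21e-05), with the folate receptor Folr1 at 4.16 ± 1.79. So were all 12 striatal markers (median 0.61, camera adjusted p = 0.0019, adjusted p = 0.587 with an estimated correlation for both lists), with the retinoic acid receptor Rarb at 0.67 ± 0.95. Markers of the hypothalamus (12 of 14, median 0.70, camera adjusted p = 0.000684) and the olfactory bulb (9 of 9, median 0.85, camera adjusted p = 0.000103) were higher as well (adjusted p = 0.587 with an estimated correlation for both). The hypothalamic call was lost without WT mock 1 (-0.045, 0.912), in males (-0.047, 0.825) or without the low-striatum pair (-0.045, 0.709). Its median was 2.24 without WT mock 2. The olfactory bulb call was lost without WT mock 1 (0.014, 0.921), in males (0.013, 0.875) or without the low-striatum pair (0.014, 0.861). Its median was 4.01 without WT mock 2 and 0.35 with a term for sex. With the replicate number as a block it was 1.39. Of these 4 lists 0 genes passed in edgeR over all genes tested and 0 adjusted over the list alone.

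Genes of astrocytes (10 of 12, median -0.25, camera adjusted p = 0.0023), of myelin (14 of 15, median -0.32, camera adjusted p = 0.00446), of excitatory forebrain neurons (10 of 12, median -0.26, camera adjusted p = 0.00109) and of the hippocampus (8 of 10, median -0.74, camera adjusted p = 0.0389) were lower in WT stress than in WT mock as well. With an estimated correlation myelin had an adjusted p = 0.678 and the others an adjusted p = 0.587, and 0 of their genes passed in edgeR over all genes tested or adjusted over the list alone. The astrocyte call was lost without WT stress 2 (-0.076, 0.102) or with a term for sex (-0.12, 0.131). The myelin call was lost without WT mock 1 (-0.088, 0.702), WT stress 1 (-0.18, 0.405), with a term for sex (0.080, 0.267), in males (-0.090, 0.492) or without the low-striatum pair (-0.088, 0.645). Its median was -0.48 without WT mock 2. The excitatory neuron call was lost without WT mock 1 (-0.043, 0.702), WT stress 2 (-0.17, 0.0667), in males (-0.044, 0.577) or without the low-striatum pair (-0.043, 0.704). Its median was -0.47 without WT mock 2. The hippocampal call was lost without WT mock 1 (0.25, 0.13), WT stress 1 (-0.53, 0.477), CAA mock 1 (-0.74, 0.0707), CAA mock 2 (-0.74, 0.0679), with a term for sex (0.11, 0.841), in males (0.25, 0.129) or without the low-striatum pair (0.25, 0.0834). Its median was -1.31 without WT mock 2 and -1.16 without WT stress 2. With the replicate number as a block the hippocampal call was lost (-0.60, 0.0878).

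edgeR and DESeq2 called 0 genes for stress in WT, and 273 had an edgeR unadjusted p under 0.05 (859 expected). The genes with the smallest p, Entpd4b at 2.28 ± 0.52, Mtcp1 at 1.87 ± 0.48, Cd74 as above, Tst at -0.69 ± 0.19 and Abca4 at 2.04 ± 0.55, had an edgeR adjusted p = 0.9999. Without WT mock 1 edgeR called 1 gene (Gm12411) and without WT mock 2 it called 2 (Slc10a4 and Th), named after their values were seen. Camera with the preset correlation called 22 lists (15 higher, 7 lower), 11 without WT mock 1 and 8 without WT stress 1, and with an estimated correlation 0. Over all genes tested 0 list genes passed in edgeR, and adjusted over the list alone 1 antigen presentation gene and 1 chemokine list gene did, and 0 in the glucocorticoid, homeostatic microglial, choroid plexus and striatal lists. Calls were lost for antigen presentation without WT stress 1 (0.163), for glucocorticoid genes without WT mock 1 (0.073, 0.275) or WT stress 1 (0.224). The antigen presentation median was 0.25 without WT mock 2 and 0.27 without WT stress 2, and the glucocorticoid median 0.15 without WT stress 2. Calls were also lost for homeostatic microglia without WT mock 2 (-0.16, 0.315) or WT stress 2 (-0.0051, 0.871), and the median was -0.51 without WT stress 1. The chemokine call was lost without WT mock 2 (-0.060, 0.639) or WT stress 1 (0.19, 0.234), and the median was 0.55 without WT mock 1 and 0.079 without WT stress 2. The choroid plexus call was lost without WT stress 2 (-0.43, 0.354), and the median was 2.87 without WT mock 1. The striatal call was lost without WT mock 1 (-0.21, 0.484) or WT stress 1 (0.16), and the median was 2.86 without WT mock 2. Without the low-striatum pair the striatal median was -0.21 (camera adjusted p = 0.0293) and the glucocorticoid median 0.073 (0.223). In males the glucocorticoid list had a median of 0.070 (camera adjusted p = 0.333). There the striatal median was -0.21 (0.495), and, as without the low-striatum pair, the choroid plexus median 2.87 and the chemokine median 0.55. With a term for sex the striatal call was lost (0.43, 0.0719), and the medians were -0.15 for homeostatic microglia, 3.44 for choroid plexus and 0.23 for chemokine genes.

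In CAA mice, homeostatic microglial genes were lower under stress in 10 of 12 (median log2 fold change -0.31, n = 2 per group, camera adjusted p = 7.49e-04, adjusted p = 0.951 with an estimated correlation). The purinergic receptor P2ry13 lay at -1.01 ± 0.28 and Gpr34 at -0.86 ± 0.27. Disease-associated microglial genes were lower in 18 of 22 (median -0.24, camera adjusted p = 0.00698), with Ccl6 at -1.03 ± 0.48 and B2m at -0.50 ± 0.23. All 15 myelin genes were lower (median -0.42, camera adjusted p = 7.49e-04, adjusted p = 0.951 with an estimated correlation for both lists), among them the galactolipid enzyme Ugt8a at -0.85 ± 0.38 and Aspa at -0.92 ± 0.42. Ribosomal protein genes were lower in 24 of 30 (median -0.19, camera adjusted p = 7.49e-04), with Rps27 at -0.88 ± 0.21. Mitochondrial genome genes were lower in 9 of 13 (median -0.35, camera adjusted p = 0.00336, adjusted p = 0.951 with an estimated correlation for both lists), with mt-Nd3 at -0.70 ± 0.23. Excitatory forebrain neuron markers were higher in 10 of 12 (median 0.47, camera adjusted p = 0.00372), with Cux2 at 0.80 ± 0.22 and the postsynaptic calmodulin-binding gene Nrgn at 0.61 ± 0.20. Circadian clock genes were higher in 13 of 16 (median 0.26, camera adjusted p = 0.00463, adjusted p = 0.951 with an estimated correlation for both lists), with the period genes Per2 at 0.68 ± 0.20 and Per3 at 0.63 ± 0.22. Fibroblast and matrix genes were higher in 15 of 18 (median 0.44, camera adjusted p = 0.00698, adjusted p = 0.951 with an estimated correlation). The member with the smallest p, the proteoglycan Dcn, lay at -1.59 ± 0.31 beside Col4a2 at 0.80 ± 0.22. Striatal markers were low in CAA mock 2 (-1.98) and the mitochondrial share was low in CAA stress 2 (6.10%), 1 library on each side of this comparison.

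edgeR called 0 genes for stress in CAA and DESeq2 14 (6 higher, 8 lower), and 1193 had an edgeR unadjusted p under 0.05. The smallest p-values, at an edgeR adjusted p = 0.696, belonged to the nuclear receptor Nr4a2 at -1.36 ± 0.23, mt-Tp at -0.84 ± 0.15, the desmosomal cadherin Dsc3 at -3.03 ± 0.55, Dcn, and Serpinb8 at 1.63 ± 0.33. Camera with the preset correlation called 10 lists (4 higher, 6 lower) and with an estimated correlation 0. Over all genes tested 0 list genes passed in edgeR, and adjusted over the list alone 2 homeostatic microglial genes, 1 ribosomal gene, 1 excitatory neuron gene and 2 fibroblast list genes (1 higher, 1 lower) did. Without CAA stress 2 the calls were lost for myelin (0.10, 0.932), ribosomal (0.054, 0.932), mitochondrial (-0.16, 0.348), excitatory neuron (0.037, 0.923) and fibroblast genes (0.17, 0.465). The medians there were -0.019 for disease-associated (camera adjusted p = 0.0457) and -0.19 for homeostatic microglia (0.0449). Without CAA mock 2 the calls were lost for disease-associated microglia (-0.13, 0.195) and myelin (-0.085, 0.366), and the medians were -0.19 for mitochondrial and 0.88 for fibroblast genes. With the low-striatum pair left out these 4 medians were the same, and camera adjusted p = 0.188 for disease-associated microglia and 0.356 for myelin. Without CAA mock 1 the calls were lost for homeostatic microglia (0.0704), circadian (0.103) and fibroblast genes (0.17, 0.925), and the medians were -0.81 for myelin and -0.12 for ribosomal genes. Without CAA stress 1 the circadian call was lost (0.0616), and the medians were, as in males, -0.50 for disease-associated microglia, -1.11 for myelin, -0.38 for ribosomal, -0.59 for mitochondrial and 0.74 for excitatory neuron genes. With a term for sex the circadian call was lost (0.11, 0.0716), and the myelin median was -0.92.

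Averaged over the genotypes, homeostatic microglial genes were lower under stress in 11 of 12 (median log2 fold change -0.30, 4 libraries against 4, camera adjusted p = 1.71e-05, adjusted p = 0.752 with an estimated correlation). P2ry13 lay at -0.65 ± 0.19 and P2ry12, the receptor that guides microglial processes, at -0.53 ± 0.20. Astrocyte genes were lower in 11 of 12 (median -0.25, camera adjusted p = 1.95e-04), with the water channel Aqp4 at -0.49 ± 0.16 and the connexin Gja1 at -0.38 ± 0.17. All 15 myelin genes were lower (median -0.33, camera adjusted p = 1.71e-05, adjusted p = 0.752 with an estimated correlation for both lists), with Opalin at -0.51 ± 0.22 and Ugt8a at -0.64 ± 0.26. Antigen presentation genes were higher in 13 of 15 (median 0.37, camera adjusted p = 6.17e-04, adjusted p = 0.752 with an estimated correlation), with Cd74 at 0.93 ± 0.30 and H2-Ab1 at 0.95 ± 0.35. Markers of the olfactory bulb (9 of 9, median 1.31, camera adjusted p = 0.000109), the choroid plexus (15 of 16, median 1.36, camera adjusted p = 0.000273), the hypothalamus (14 of 14, median 0.70, camera adjusted p = 0.000617) and the striatum (12 of 12, median 0.65, camera adjusted p = 0.00107) were higher under stress beside these lists (adjusted p = 0.752 with an estimated correlation for each). Hippocampal markers were lower (8 of 10, median -0.95, camera adjusted p = 0.00745, adjusted p = 0.752 with an estimated correlation). The hippocampal call was lost without WT mock 1 (-0.24, 0.197), WT stress 1 (-0.84, 0.109), in males (-0.54, 0.0833) or without the low-striatum pair (0.039, 0.717). Its median was -0.50 without CAA mock 2. The choroid plexus call was lost without WT stress 2 (0.036, 0.656) or CAA stress 1 (0.40, 0.413). Its median was 0.88 in males. The hypothalamic call was lost without WT mock 1 (0.43, 0.08), CAA mock 2 (0.37, 0.0708), CAA stress 1 (0.50, 0.142), in males (0.16, 0.787) or without the low-striatum pair (0.078, 0.717). Its median was 1.30 without WT mock 2, 0.44 without WT stress 2 and 2.11 without CAA mock 1. The striatal call was lost without WT mock 1 (0.21, 0.197), CAA mock 2 (0.26, 0.111), CAA stress 1 (0.38, 0.0987) or in males (0.0026, 0.789). Its median was 1.88 without WT mock 2 and 1.49 without CAA mock 1. Without the low-striatum pair it was -0.17 (camera adjusted p = 0.0099). The olfactory bulb median was 0.84 without WT mock 1, 3.08 without WT mock 2, 0.58 without CAA stress 2 and 0.77 without the low-striatum pair. Of these 5 lists 0 genes passed in edgeR over all genes tested and, adjusted over the list alone, 0. Fkbp5, a chaperone gene that glucocorticoids induce, lay at 46.8 ± 10.2 CPM in mock and 58.0 ± 3.78 CPM under stress (SD, n = 4; log2 fold change 0.32 ± 0.14, edgeR adjusted p = 0.92). Gfap had a log2 fold change of -0.74 ± 0.21 (edgeR adjusted p = 0.92).

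For that average edgeR called 0 genes and DESeq2 3 (Entpd4b higher, Nr4a2 and Grp lower). In edgeR 657 genes had an unadjusted p under 0.05 (859 expected). Entpd4b, a nucleotide hydrolase gene, had a log2 fold change of 2.50 ± 0.38 (edgeR adjusted p = 0.831, DESeq2 adjusted p = 7.34e-06), but its near copy Entpd4 held 0 or 1 counts per library, so how reads were divided between them is uncertain. Nr4a2 lay at -0.88 ± 0.16, Dsc3 at -1.87 ± 0.38, the gastrin-releasing peptide gene Grp at -1.36 ± 0.28 and Hopx at -0.61 ± 0.13. Without WT mock 1 edgeR called 1 gene, and without WT mock 2 it called 4, among them Grp (-1.63, edgeR adjusted p = 0.0360). Camera with the preset correlation called 15 lists (8 higher, 7 lower) and with an estimated correlation 0. Of the cell type and antigen presentation genes 0 passed in edgeR over all genes tested and 0 adjusted over the list alone. The antigen presentation call was lost without WT stress 1 (0.0971) or CAA mock 1 (0.207), and its median was 0.18 without WT mock 2. The homeostatic median was -0.48 without WT stress 1 and -0.17 without WT stress 2. The astrocyte median was -0.15 without CAA mock 2, -0.42 without CAA stress 1 and -0.15 without CAA stress 2. The myelin median was -0.52, -0.15, -0.70 and -0.098 without CAA mock 1, CAA mock 2, CAA stress 1 and CAA stress 2. Without the low-striatum pair the myelin list had a median of -0.017 (camera adjusted p = 0.317). There the antigen presentation median was 0.60. In males the medians were -0.44 for astrocyte and -0.60 for myelin genes.

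Whether the stress effect differed between CAA and WT was tested as an interaction, positive where stress raised a gene more in CAA. Excitatory forebrain neuron markers were positive in 11 of 12 (median 0.51, camera adjusted p = 6.44e-06), with Cux2 at 1.17 ± 0.31 and Nrgn at 0.91 ± 0.28. Circadian clock genes were positive in 14 of 16 (median 0.33, camera adjusted p = 4.58e-04, adjusted p = 0.904 with an estimated correlation for both lists), with Per2 at 1.04 ± 0.28 and the clock output gene Dbp at 1.74 ± 0.56. Synaptic genes were positive in 12 of 20 (median 0.19, camera adjusted p = 0.0317), with the scaffold genes Bsn at 0.70 ± 0.31 and Shank1 at 0.63 ± 0.28. Disease-associated microglial genes were negative in 17 of 22 (median -0.24, camera adjusted p = 0.0179, adjusted p = 0.904 with an estimated correlation for both lists), with Clec7a at -3.80 ± 1.51 and Gpnmb at 1.61 ± 0.74. Mitochondrial genome genes were negative in 10 of 13 (median -0.39, camera adjusted p = 0.0179, adjusted p = 0.904 with an estimated correlation), with mt-Nd3 at -0.72 ± 0.32. These 5 lists were the ones called with the preset correlation, and with an estimated correlation 0 were called. Without the low-striatum pair the calls were lost for microglial (-0.14, 0.405), mitochondrial (-0.17, 0.34) and synaptic genes (0.050, 0.805). There the excitatory neuron median was 0.22 (camera adjusted p = 0.0254) and the circadian median 0.18 (0.00945). Over all genes tested 0 of their genes passed in edgeR while adjusted over the list alone 2 excitatory neuron genes did.

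edgeR called 0 genes for the interaction and DESeq2 1 (Xist), and 595 had an edgeR unadjusted p under 0.05 (859 expected). The smallest p-values, at an edgeR adjusted p = 0.995, belonged to mt-Tp at -1.01 ± 0.21, the radial glial lipid carrier Fabp7 at -1.60 ± 0.33, Ccl27a at 4.36 ± 1.02, Car7 at 1.37 ± 0.35 and Tspoap1 at 1.04 ± 0.28. Ccl27a is annotated more than once, so its reads are uncertain. Without WT mock 2 edgeR called 1 gene (Slc10a4). The microglial call was lost without WT stress 1 (0.0908), CAA mock 2 (0.154) or CAA stress 2 (0.0902), and the mitochondrial call without WT mock 1 (0.0997), WT stress 1 (0.121) or CAA stress 2 (0.492). The synaptic call was lost without WT mock 1 (0.114), WT stress 2 (0.208), CAA mock 2 (0.400) or CAA stress 2 (-0.027, 0.635). The excitatory neuron median was 0.27 without CAA stress 2 (camera adjusted p = 0.0479) and 0.86 without CAA stress 1. The circadian median was 0.17, 0.56, 0.16 and 0.52 without WT mock 1, WT mock 2, WT stress 1 and WT stress 2, and with a term for sex it was 0.18 (camera adjusted p = 0.0507). Without CAA stress 1 the medians were -0.53 for microglial, -0.63 for mitochondrial and 0.37 for synaptic genes, and without CAA mock 1 the synaptic median was 0.45. The count of lists was 10, 15, 10, 13, 12 and 17 without WT mock 1, WT mock 2, WT stress 2, CAA mock 1, CAA mock 2 and CAA stress 1. Without CAA mock 2 the medians were -0.16 for microglial and 0.095 for synaptic genes, and without CAA stress 2 -0.11 for microglial and -0.22 for mitochondrial genes. The synaptic median was 0.075 without WT mock 1 and 0.29 with a term for sex. The microglial median was -0.43 with a term for sex and -0.45 in males, where the circadian median was 0.19.

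Neutrophil genes were near the limit of detection. Mpo, the myeloperoxidase of neutrophil granules, had 0 to 6 counts per library and Padi4, the enzyme that citrullinates histones in extracellular traps, 0 to 2; Elane had 0 to 3, Ly6g 0 to 2 and Ctsg 0, and none of these 5 entered the test. A count of 0 allows up to 3 counts, or 0.159 to 0.174 CPM in these libraries, and covers counting error only. The 9 tested members (Ncf1, Itgam, Csf3r, Anxa1, Prtn3, Mmp9, Lcn2, S100a9 and S100a8) were higher in CAA mock than in WT mock in 8 of 9 (median 0.58, camera adjusted p = 0.0295, adjusted p = 0.587 with an estimated correlation). The granule protease Prtn3 lay at 1.30 ± 0.51 and the growth factor receptor Csf3r at 0.58 ± 0.31. Over all genes tested 0 of the 9 passed in edgeR and adjusted over the list alone 0. That call was lost without WT mock 2 (0.35, 0.342) and without CAA mock 2 (-0.057, 0.485), and the median was 1.02 without WT mock 1, 1.02 in males and 0.32 without the low-striatum pair (0.182). Other myeloid genes were higher beside them, the disease-associated microglial list as above and border macrophage and monocyte genes (7 of 9, median 0.46, camera adjusted p = 0.0306, adjusted p = 0.587 with an estimated correlation; 0 passed in edgeR over all genes tested and 0 adjusted over the list alone). The border macrophage call was lost without WT mock 1 (0.64, 0.0573), WT mock 2 (0.21, 0.142), CAA mock 2 (0.25, 0.385), with a term for sex (0.50, 0.172), in males (0.64, 0.0607) or without the low-striatum pair (0.25, 0.378). Itgam, Csf3r and Ncf1 are known from other myeloid cells too. Stress gave a median of 0.36 in WT (7 of 9 higher, camera adjusted p = 0.154) and of -0.18 in CAA (4 of 9 higher, mean 0.10, camera adjusted p = 0.832), where the median and the mean differ in sign. The interaction had a median of -0.52 (camera adjusted p = 0.334). S100a8 and S100a9, the calprotectin subunits, had averaged log2 fold changes of 1.24 ± 0.80 and 1.16 ± 0.79 between CAA and WT. Both were high in CAA mock 2 and CAA stress 1 alone. There S100a9 had 2.03 and 1.69 CPM, against 0.0584 in CAA mock 1 and 0.269 to 0.606 in WT. The averaged comparison gave the list a median of 0.29 for CAA (6 of 9 higher, camera adjusted p = 0.0878) and of 0.14 for stress (5 of 9 higher, camera adjusted p = 0.635).

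**Figure D3:**
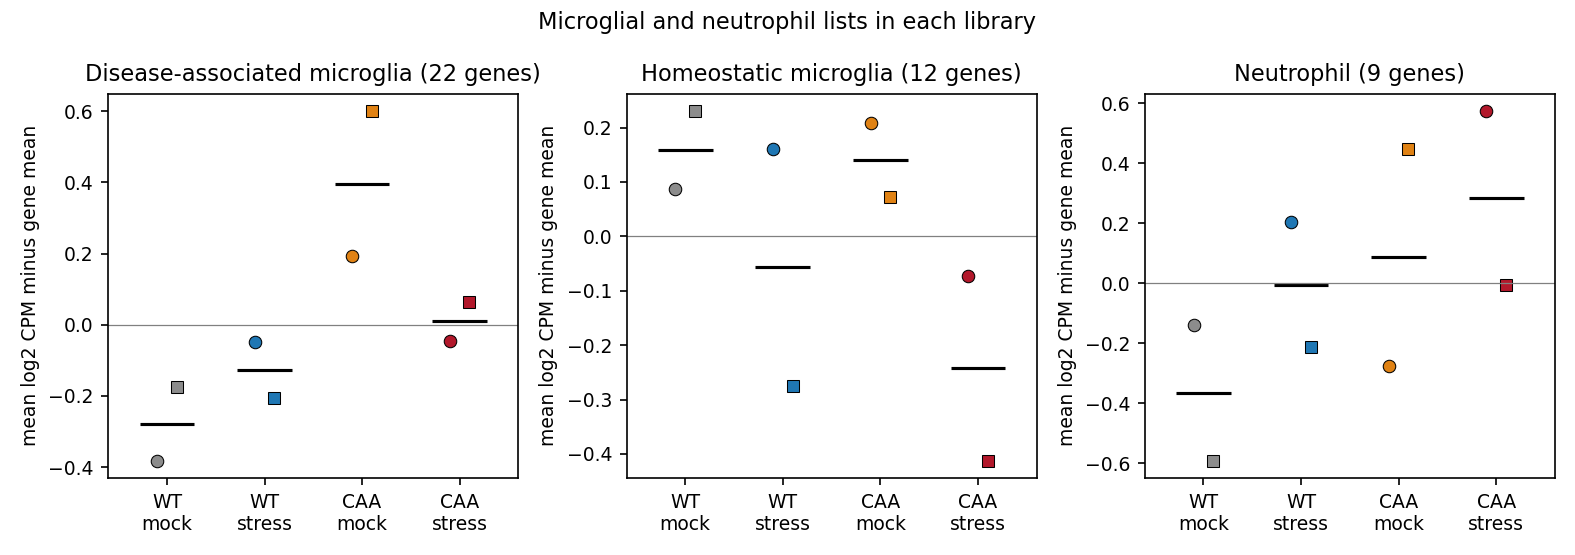
Mean log2 CPM of disease-associated microglial (22 genes), homeostatic microglial (12) and neutrophil genes (9) in each of the 8 libraries, each gene minus its mean over the libraries. The microglial list around amyloid is highest in CAA mock replicate 2 (0.60), and the neutrophil list in CAA stress replicate 1 (0.57).

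Across the 17182 genes, which are not independent replicates, the stress effects in WT and in CAA had Pearson's r = 0.096 and Spearman's rho = 0.0945, and the CAA effects under mock and under stress had r = 0.169 and rho = 0.174. The compared effects shared no library but shared each gene's estimate of spread, so the lists below are not independent. At an unadjusted p under 0.05, 43 genes were higher in CAA both under mock (265) and under stress (711), where 10.97 are expected from independent lists, and 37 were lower in both (423 and 702), where 17.3 are expected. Under stress 11 genes were higher in both genotypes (150 and 632, 5.52 expected) and 10 lower in both (123 and 561, 4.02 expected). For the stress effects r and rho were 0.0557 and 0.107 without WT mock 1, 0.121 and 0.0359 without WT mock 2, 0.16 and 0.217 without WT stress 1, -0.014 and -0.0893 without WT stress 2. They were 0.156 and 0.0972 without CAA mock 1, 0.00277 and 0.0518 without CAA mock 2, 0.0182 and -0.0113 without CAA stress 2. For the CAA effects r and rho were 0.267 and 0.247 without WT mock 1, 0.016 and 0.0409 without WT mock 2, 0.109 and 0.12 without WT stress 1, 0.107 and 0.0332 without CAA mock 1. They were 0.105 and 0.219 without CAA mock 2, -0.0283 and -0.0305 without CAA stress 1, 0.238 and 0.305 without CAA stress 2. In males they were -0.0305 and 0.141 for stress and -0.00503 and 0.0636 for CAA.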

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

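The tests by sex, by region content, of 1 library and on neighbouring genes were chosen only after the results were seen. So were those of genotype or stress as the source of region markers and of more microglia of every kind. Those on random lists and other splits were not. Of 100 groups of 4 libraries examined over 25 series of values, 14 held a library far from the other 3; chance gives about 1 in 20 groups, or 5.

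Wdfy1 rose and Ngef fell in CAA, and within the CAA libraries Ngef was far lower in CAA mock replicate 2 (gap to the nearest library 0.894 of the range). Sex and region content are argued against. The 2 genes kept at least 95.4% of their log2 fold change in males and at least 94.0% without the low-striatum pair. Both genes lie on chromosome 1, and a stretch inherited from another strain may have come with the CAA genotype, but the mean absolute t of their 187 tested neighbours within 10 Mb (0.873; median of 13411 stretches 1.01) was at percentile 0.626 on a scale of 0 to 100. A linked variant that acts on few genes cannot be told apart from an effect of the CAA genotype itself, because the labels give no strain and every CAA library carries both. Of the 35 splits of the 8 libraries into 4 and 4, 3 called as many genes as CAA against WT (2, highest other 43). Chance is thus not excluded for a count of that size. That count does not test the 2 genes themselves (edgeR adjusted p = 5.15e-05 and 4.44e-04). The split with 43 genes set apart libraries low in olfactory bulb markers (WT mock 1, CAA mock 1, CAA mock 2, CAA stress 1). Olfactory bulb markers thus went partly with genotype, and 6 of the 9 tested were among the 43.

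Markers of brain regions lay apart between libraries of 1 kind: within WT, replicate 1 of mock was far from the other 3 libraries for striatal (0.853), hypothalamic (0.897), brainstem (0.860) and olfactory bulb markers (0.912), and within stress, CAA stress replicate 1 for brainstem markers (0.901). Sex as the whole source is argued against for choroid plexus, hippocampal, striatal, thalamic and cerebellar markers, where the male libraries spanned 100%, 97.5%, 93.7%, 92.5% and 87.0% of the range. Genotype and stress as the whole source are argued against for these and hypothalamic markers, with 81.7%, 64.2%, 74.1%, 83.4%, 76.5% and 60.1% of the sum of squares within groups (57.1% with no effect). With 2 libraries per group these shares do not exclude a smaller effect of genotype or stress. Sex cannot be told apart for hypothalamic (70.9%), brainstem (64.1%) and olfactory bulb markers (78.6%), nor genotype and stress for brainstem (50.3%) and olfactory bulb markers (51.8%), as these shares are neither high nor low. A different content of brain regions goes with the gap between replicates. That gap topped the 95th percentile of 10000 random lists for 8 of 8 region lists but also 26 of 35 others. Median gaps were 1.24 and 0.264. For stress against mock the real split called 0 genes, which all 35 reach, so that count says nothing on chance. As many lists were called by 22 of the 35 (13, highest other 24), and for CAA against WT by 6 (18, highest other 24). Chance is thus not excluded for the lists. These counts come from a fit of 2 groups of 4.

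Disease-associated microglial genes were higher in CAA (camera adjusted p = 2.23e-05, adjusted p = 0.601 with an estimated correlation), and the stress effect on them was lower in CAA than in WT (interaction, camera adjusted p = 0.0179, adjusted p = 0.904 with an estimated correlation and 0.405 without the 2 libraries low in striatal markers). That 1 library decides the CAA result is argued against by its lowest median without any 1 library, 0.17, with the highest camera adjusted p at 0.00442. Sex as the whole source is argued against, since the call held in the male libraries alone (camera adjusted p = 0.00131), while their lower median, 0.16, leaves sex open as a part of the size; a term for sex (median 0.25, camera adjusted p = 7.54e-06) can hardly move this average, since each genotype had 1 female library. A higher share of microglia of every kind stays open, although the homeostatic median was -0.19 in CAA against WT (-0.013 under mock and -0.19 under stress), because the difference between the disease-associated and the homeostatic lists had an exact two-sided permutation p = 0.0857 (0.254 ± 0.288 in CAA and -0.254 ± 0.241 in WT, SD, n = 4), so that it cannot be told apart from a change of microglial state. Of the 35 splits 3 gave as small a camera p (-log10 p 5.87, highest other 7.68), so chance is not excluded.

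The interaction test with the preset correlation called 4 more lists: excitatory forebrain neurons (camera adjusted p = 6.44e-06), circadian clock (4.58e-04), synaptic (0.0317) and mitochondrial genome genes (0.0179). None was called with an estimated correlation (adjusted p = 0.904 for each). Without the low-striatum pair the synaptic (0.805) and mitochondrial calls (0.34) were lost. App in WT mock 1 (0.862) and mitochondrial genome genes in WT mock 2 (0.894) lay far from the other mock libraries. Fkbp5 in CAA mock 2 lay far from the other CAA libraries (0.836), and S100a9 in CAA stress 1 from the other stress libraries (0.897). Xist lay far from the others in WT mock replicate 1 (0.995 among WT and 0.995 among mock libraries) and in CAA stress replicate 1 (0.999 among CAA and 0.999 among stress libraries).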

How the results depend on the processing

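The term for sex, the male libraries alone, the omission of the 2 libraries low in striatal markers, the list medians and the single genes named in this part were chosen only after the results were seen. Of the values of single genes, 322 of 336 kept their direction and side of the threshold when 1 library was left out (10 weaker, 1 stronger, 3 in the opposite direction), and 346 of 398 under the other settings (43 stronger, 9 weaker). Of the list medians 434 of 552 did when 1 library was left out (102 weaker, 16 opposite) and 207 of 276 under the other settings (55 weaker, 14 opposite). Of the counts and correlations 95 of 128 stayed within 1.5 times or the same sign when 1 library was left out (31 moved, 2 opposite) and 61 of 108 under the other settings (44 moved, 3 opposite). Where a value below changed, the cause was not tested, except that fewer libraries were used where libraries were left out. Genes at a few counts per library cannot show small changes at this depth.

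Without the filter on low counts edgeR called 11 genes for stress in WT, 112 for stress in CAA, 82 for CAA under mock, 120 for CAA under stress, 17 for the interaction, 49 for stress averaged and 223 for CAA averaged. DESeq2 called 14 for stress in CAA, 19 for CAA under mock, 11 for CAA under stress, 1 for the interaction, 3 for stress averaged and 49 for CAA averaged. On log2 FPKM, with a pseudocount of 1 or of 0.1, limma called 1 gene for CAA under mock (Wdfy1, without Ngef) and 0 for CAA under stress, beside 2 and 2 in edgeR on counts. With only the libraries compared, edgeR called 1 gene for CAA under mock (Wdfy1, without Ngef); that setting does not apply to the interaction and the averages.

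The male libraries alone gave 1 gene for stress in WT, 8 for stress in CAA, 8 for CAA under mock, 1 for CAA under stress (Wdfy1), 1 for stress averaged and 7 for CAA averaged, and 16 lists for stress in CAA and 23 for the interaction. Omp, Cdhr1 and Eomes, on the olfactory bulb list, and Ms4a15, on no list, were among the 8 genes for stress in CAA and the 8 for CAA under mock. Omp was the gene for stress averaged, and Omp, Cdhr1 and Ms4a15 were among the 7 for CAA averaged. There the median was -0.020 for glucocorticoid genes in CAA averaged and -0.21 for striatal and -0.047 for hypothalamic markers under stress in WT, 0.25 for hippocampal markers there, and -0.11 for nuclear respiratory chain genes in CAA under stress. Across genes r turned to -0.0305 for stress and -0.00503 for CAA, while rho was 0.141 and 0.0636. With a term for sex, 2 genes were called for stress in CAA (Eomes and Omp), 7 for CAA under mock (Eomes, Omp, Cdhr1 and Ms4a15 among them) and 1 for CAA under stress (Wdfy1), and 16 lists for stress in CAA and 20 for the interaction. For stress in WT it gave medians of 0.080 for myelin and 0.11 for hippocampal genes. Without the 2 libraries low in striatal markers 1 gene was called for stress in WT (Gm12411), 1 for stress in CAA (Gapdh, -3.85), 1 for the interaction (Gapdh, -4.48) and 4 for CAA averaged (Gapdh, 3.20, with Wdfy1, Ngef and Nr2f2), where the counting of Gapdh is uncertain, and 11 lists for CAA under mock and 9 for the interaction. There the medians under stress in WT were -0.21 for striatal, -0.045 for hypothalamic and 0.25 for hippocampal markers. Under averaged stress the median was 0.039 for hippocampal markers and -0.17 for striatal markers, that of brainstem markers for CAA under mock -0.21 and that of immediate early genes for CAA under mock 0.052. Over genes of at least 10 mean CPM the stress effects had r = -0.0619 and rho = 0.0813. With an estimated correlation camera called 0 lists in each of the 7 comparisons, against 22, 10, 21, 7, 5, 15 and 20 with the preset one.

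When each library was left out in turn, edgeR called 0 to 2 genes for stress in WT, 0 to 0 for stress in CAA, 1 to 3 for CAA under mock, 0 to 2 for CAA under stress, 0 to 1 for the interaction, 0 to 4 for stress averaged and 2 to 5 for CAA averaged. Camera called 8 to 23, 10 to 14, 13 to 22, 8 to 14, 6 to 17, 12 to 20 and 12 to 25 lists in the same order. Across genes r ran from -0.014 to 0.16 for stress and from -0.0283 to 0.267 for CAA. Medians that changed sign ran, for stress in CAA, from -1.11 to 0.10 (myelin) and from -0.38 to 0.054 (ribosomal). They ran for CAA under mock from -0.057 to 1.02 (neutrophil) and from -0.012 to 0.82 (myelin), and for stress in WT from -0.21 to 2.86 (striatum), from -0.43 to 2.87 (choroid plexus) and from -0.060 to 0.55 (chemokines). Those of hypothalamic markers ran from -0.44 to 3.08 for CAA averaged, from -1.13 to 4.98 for CAA under mock and from -0.045 to 2.24 for stress in WT. Thalamic markers for CAA under mock ran from -0.035 to 1.13, and for stress in WT border macrophage genes from -0.28 to 0.88 and erythrocyte genes from -0.11 to 1.69. Hippocampal markers for stress in WT ran from -1.31 to 0.25, and nuclear respiratory chain genes for CAA under stress from -0.11 to 0.41. For the interaction the range was -0.027 to 0.45 (synaptic). Thy1 for stress averaged ran from -0.035 to 0.22 and App for CAA averaged from -0.047 to 0.081.

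With the replicate number as a replicate block edgeR called 0, 0, 2, 2, 0, 0 and 2 genes and camera 21, 11, 23, 8, 6, 15 and 20 lists, in that order, and no count moved by over 1.5 times. Deviations of libraries with the same number correlated at -0.13, -0.27, 0.14, -0.02, -0.00036 and -0.08 between the 6 pairs of groups, so the numbers do not pair the samples.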

Other observations

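The single genes in this part were chosen only after their values were seen; the tests of lists were not. Hypothalamic peptide genes were high in 2 libraries of different groups. Pmch, which encodes melanin-concentrating hormone, lay at 17.9 CPM in CAA mock replicate 1 and 28.6 CPM in CAA stress replicate 1 and at most at 0.493 CPM in the other 6, and Hcrt, the orexin gene, lay at 13.2 and 10.9 CPM in the same 2 libraries. Ttr, the transthyretin gene of the choroid plexus, ranged from 2.65 to 449 CPM. Ccl2 reached 4.11 CPM in WT stress replicate 1, the library with the highest level of erythrocyte genes (1.67), and at most 0.606 CPM in the others.

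Gapdh had 1894, 38, 47, 73, 1584, 382, 134 and 103 counts in the 8 libraries (WT mock, WT stress, CAA mock, CAA stress, replicate 1 before 2), beside 10549 to 12544 for Actb. Gapdh has many processed pseudogenes, so how its reads were counted is uncertain.

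Heat shock genes under averaged stress had a camera adjusted p = 0.134 (Hspa1a 0.59 ± 0.21), genes of the unfolded protein response 0.678 and genes of the stress axis 0.239 (Hsd11b1, which regenerates active glucocorticoid, -1.03 ± 0.33). Amyloid processing genes between CAA and WT had a camera adjusted p = 0.12, with 12 of 19 higher, and pericyte genes 0.228.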
